A study of Danio rerio with 19 samples.

How the data were processed

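The deposited files hold 1 table of gene counts per library for 19 libraries, each from 1 larval zebrafish head with the eyes removed, and per the labels the libraries fall into 2 lines (scn1lab and dyrk1a) with 3 genotypes each: homozygous mutant (HOM), heterozygous (HET) and wild type (WT). Per the submitters' processing notes, reads were trimmed with Trim Galore 0.5.0, aligned to GRCz11 with HISAT2 2.1.0 and summarized with StringTie 1.3.3b, and DESeq2 1.22.1 was used for differential expression. The deposited values are raw counts: whole numbers without scaling, given for the same 32020 gene IDs in every table. Gene symbols came from the supplied table of gene names, which holds a symbol for 28975 of these IDs and none for 3045. Because 5966 IDs share their symbol with another ID, the ID stands beside such a symbol where a gene is first named. Total counts ran from 15.1 to 29.9 M per library. The labels' protocols name 2 RNA extraction kits without saying which library had which, so the kit was not used here.

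All tests were run in R 4.3.3. Genes were filtered with filterByExpr, scaled by TMM and tested in edgeR 4.0.16 with robust quasi-likelihood F tests (two-sided), with 1 fit for the 9 scn1lab libraries and 1 for the 10 dyrk1a libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. HOM was compared with WT, HET with WT and HOM with HET in each line, and the difference between the lines in the HOM effect (dyrk1a minus scn1lab) was tested in 1 fit of all 19 libraries. HOM and HET are compared with the same 3 WT libraries within a line, so these comparisons are not independent, and their overlap was not computed. The 2 lines share no libraries. Changes are log2 fold changes with a standard error (SE) computed back from the test, as the size of the log2 change divided by the square root of F. Levels in CPM use TMM-scaled library sizes, and groups are given as mean ± standard deviation (SD). Where every library of a group holds 0 counts, the fold is a lower bound computed against a floor of 3 counts per library. Shares of counts carry 95% Wilson intervals that reach at most 0.02 percentage points from the share. These intervals and floors cover counting error only.

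Before the data were examined, 38 gene lists were fixed: 37 could be tested and the list of mitochondrially encoded genes matched 0 genes. The lists are dopaminergic, serotonergic and noradrenergic, GABAergic, glutamatergic, voltage-gated sodium channels, potassium and calcium channels, immediate early genes, synapse, neuropeptides, pituitary hormones, oligodendrocyte and myelin, astroglia and radial glia, cell proliferation, p53 and apoptosis, microglia and macrophage, neutrophil, complement, interferon and antigen presentation, cytokines and inflammation, circadian clock, glucocorticoid and cellular stress, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, autism-associated genes, telencephalon, cerebellum, photoreceptor and retina, lens, skeletal muscle, cartilage and bone, skin and epithelium, erythrocyte, digestive organs, endothelium, and pigment cells. Of 1593 list names, 1087 matched a symbol directly, 372 matched after removal of the paralog letter and 131 matched none. The other 3 entries, for ribosomal proteins, mitochondrially encoded genes and lens, are patterns matched against the symbols. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the 37 lists. Each list was also tested with the correlation estimated from the data and with the self-contained test fry. "Adjusted over the list alone" means Benjamini-Hochberg adjustment of the edgeR p-values among the members of that list. A list score is the mean over members of log2(CPM + 1) in a library, compared between groups by exact two-sided permutation tests. For 3 against 3 libraries the smallest possible p is 0.1.

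The rule for named genes was fixed together with the lists. It takes the targeted genes in every group. For HOM against WT it takes the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean CPM of at least 1, no overlap between the groups and a symbol that is not a clone name, and for the other comparisons up to 4 in each direction. It takes up to 3 members past the threshold per list, up to 10 genes called in HOM of both lines in the same direction and up to 4 in opposite directions, and up to 4 in each direction for the difference between the lines. Where no gene meets the rule, the 3 with the smallest unadjusted p are given as not past the threshold, and for both lines together the 3 with the smallest larger unadjusted p of the 2 lines. Other genes were chosen after their values were seen: up to 3 members per list that passed when adjusted over the list alone, genes singled out where few passed (si:dkey-73p2.2 and zgc:122979), genes that DESeq2 called in both lines, and ela2l as the most abundant digestive gene. A gene that met this rule is not reported here.

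Alternatives planned before the files were seen were RLE size factors, upper quartile factors, no filter, a stricter filter (CPM of at least 1 in at least 3 samples), DESeq2 1.42.0, only the compared groups in the fit, all 19 libraries in 1 fit, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a minimum change of 1.5-fold, list members shared with other tissues left out, and each library left out. Alternatives chosen after seeing the data were the log2 share of digestive-organ counts as a covariate, leaving out libraries in which that share exceeded 2%, limma with library quality weights, and fry. Splits of the libraries into groups of the same sizes were counted, with the real grouping among them. All were used where there were 100 or fewer, and otherwise 100, of which all but the real grouping were drawn at random. The overlap and correlation between the lines were computed on 20310 genes tested in both. The correlation was tested by an exact one-sided permutation test over 700 relabellings, and the DESeq2 overlap by Fisher exact tests over genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

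The methods were tested on simulated data in which 200 genes were changed by known folds. In the simulated scn1lab HOM against WT comparison (20837 genes), edgeR recovered 2.99% of 2-fold, 5.97% of 4-fold and 75.8% of 16-fold changes and called 3 unchanged genes, and DESeq2 recovered 8.96%, 49.3% and 89.4% and called 59. In the simulated dyrk1a HOM against WT comparison (20495 genes), edgeR recovered 10.4%, 50.7% and 86.4% and called 3 unchanged genes, and DESeq2 recovered 23.9%, 70.1% and 90.9% and called 60. In simulated lists camera found the raised list (adjusted p = 1.4e-26) and called 0 of the others. The simulated genes were drawn independently of each other, so this does not test for false list calls where genes vary together. All 21 pairs of libraries within a group were checked for duplicated samples, and none came close to the spread of repeated sequencing (lowest chi-square per degree of freedom 35.6). A check of genes linked to the mutated loci was void and was not run, because only 69.5% of the tested genes in scn1lab and 70.0% in dyrk1a could be placed on a chromosome (80% were required).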

Results

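Gene expression was measured by bulk RNA-seq in larval zebrafish heads without eyes, 1 head per library, in 2 lines with mutations in autism risk genes. The scn1lab line carries a deletion in a voltage-gated sodium channel gene, and the dyrk1a line carries deletions in both copies of a protein kinase gene. Libraries came from homozygous (HOM), heterozygous (HET) and wild-type (WT) larvae: 3 of each genotype in scn1lab, and 4 HOM, 3 HET and 3 WT in dyrk1a. Total counts in M (mean ± SD) were 20.8 ± 2.3 in scn1lab HOM, 22 ± 7.5 in HET and 24.5 ± 0.9 in WT. In dyrk1a they were 19.1 ± 2.4 in HOM, 23.7 ± 4.3 in HET and 21.7 ± 2.6 in WT.

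The libraries differed in how much RNA of other tissues they held. Genes of digestive organs took 14.5%, 0.055% and 17.7% of the counts in scn1lab HOM1 to HOM3, 4.23%, 16.1% and 1.38% in HET1 to HET3, and 0.45%, 1.37% and 0.089% in WT1 to WT3. In dyrk1a that share was 0.13 ± 0.167% in HOM (n = 4) and 0.0843 ± 0.115% in WT (n = 3), and it reached 6.26% in HET4. The pancreatic elastase gene ela2l alone stood at 25100 and 33400 CPM in scn1lab HOM1 and HOM3, against 70.4 CPM in HOM2. Ribosomal protein genes took 20% of the counts in scn1lab HET3. Synapse genes took 0.151 ± 0.0612% in scn1lab HOM, 0.215 ± 0.119% in HET and 0.517 ± 0.0853% in WT (n = 3 each). Photoreceptor genes took 0.051%, 0.172% and 0.058% in scn1lab HOM1 to HOM3 and 0.075% in WT1 and 1.56% in WT2, and WT3 lay above all HOM libraries. Skin genes took 6.12 ± 2.2% and 4.57 ± 1.14% in scn1lab HOM and WT, and the lens share was highest in scn1lab HOM2 at 0.172%.

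**Figure D1:**
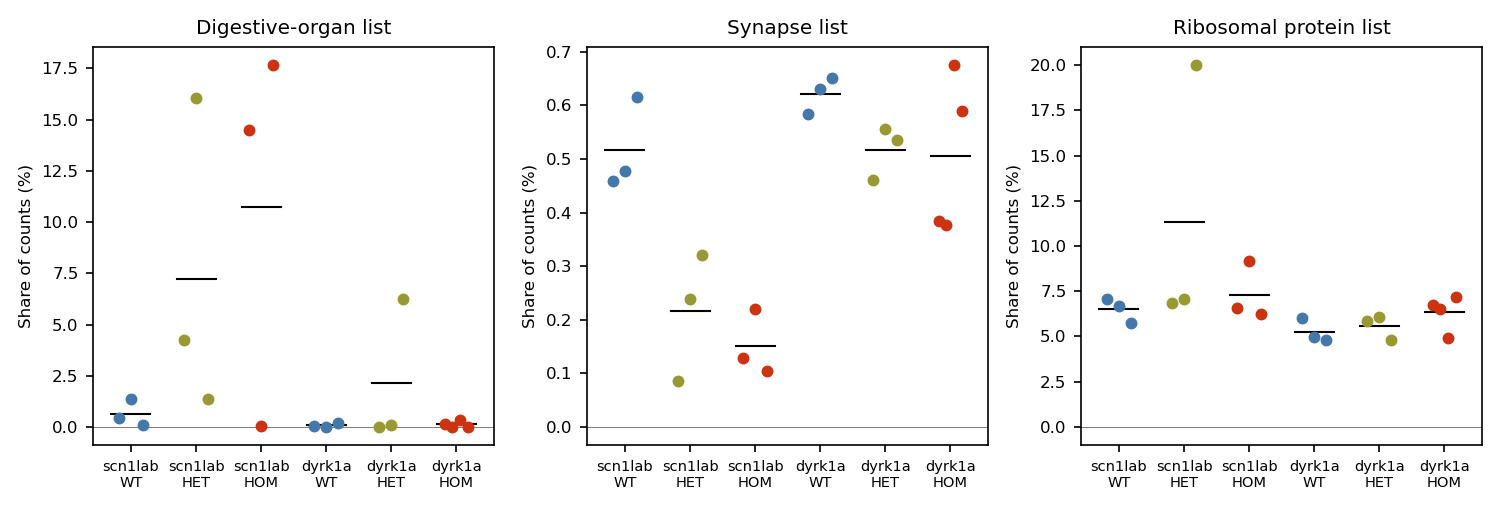
Share of each library's counts held by the digestive organ, synapse and ribosomal protein lists. Each point is 1 library and the line is the group mean.

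The targeted genes were measured first. In the scn1lab line, scn1lab (ENSDARG00000062744) stood at 14.7, 14 and 5.75 CPM in HOM1 to HOM3. It stood at 4.91, 9.41 and 14.5 CPM in HET1 to HET3 and at 15.2, 13.9 and 16.6 CPM in WT1 to WT3. Its log2 change was -0.41 in HOM (SE 0.46, edgeR adjusted p = 0.666) and -0.67 in HET (SE 0.46, adjusted p = 0.524). In the dyrk1a line, DYRK1A (ENSDARG00000023814) stood at 44.6, 43.4, 53.5 and 65.2 CPM in HOM1, HOM2, HOM3 and HOM5. It stood at 39.9, 49.7 and 50.4 CPM in HET2 to HET4 and at 40.4, 38.2 and 42.1 CPM in WT1, WT2 and WT4. DYRK1A (ENSDARG00000063570) stood at 16.9, 23.3, 26.8 and 7.68 CPM in HOM, 21.4, 7.65 and 17.8 CPM in HET, and 9.61, 19.2 and 12.2 CPM in WT, in the same order. Their log2 changes in HOM were 0.36 (SE 0.17, adjusted p = 0.655) and 0.45 (SE 0.46, adjusted p = 0.876). A small deletion need not lower a transcript's level, so these counts do not check the genotype labels, and the IDs were not assigned to the dyrk1aa and dyrk1ab copies here.

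The comparison of scn1lab HOM with WT asks what loss of this sodium channel does to the larval head. The following genes that nerve cells use for transmission, picked after their values were seen, were lower in HOM, none past the threshold in the main fit. SNAP25 (ENSDARG00000058117), part of the machinery that fuses synaptic vesicles, was at 94.1 ± 15.4 CPM in HOM and 408 ± 118 CPM in WT (n = 3 each; log2 change -2.11, SE 0.45). SYT2 (ENSDARG00000025206), a calcium sensor of vesicle release, was at 13.8 ± 2.76 and 68.9 ± 12.8 CPM (-2.32, SE 0.48). GAD1 (ENSDARG00000027419), which makes GABA, was at 40.2 ± 12.9 and 156 ± 14.6 CPM (-1.96, SE 0.52). For all of them every HOM library lay below every WT library, and the edgeR adjusted p over all genes was 0.154, 0.149 and 0.16. With only the 6 HOM and WT libraries in the edgeR fit, the adjusted p was 0.0208, 0.0188 and 0.021.

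As groups, the neuronal lists fell in scn1lab HOM by camera. The synapse list had a median log2 change of -1.37 (adjusted p = 1.4e-16): 0 of 73 members passed over all genes, and adjusted over the list alone 17 passed as lower and 1 as higher. The GABAergic list (-1.47, adjusted p = 8.1e-10) had 12 of 39 members lower when adjusted over the list alone and 0 over all genes. The glutamatergic list (-1.17, adjusted p = 1.2e-09) had 1 of 45 and 0. The potassium and calcium channel list (-1.16, adjusted p = 4.7e-14) had 4 of 62 and 0, and the voltage-gated sodium channel list (-1.06, adjusted p = 7.1e-06) 0 of 18 and 0. With an estimated correlation each of these 5 lists had adjusted p = 0.271. The dopaminergic list (-0.85, adjusted p = 2.1e-04) had adjusted p = 0.309 with an estimated correlation and the serotonergic and noradrenergic list (-0.69, adjusted p = 4.1e-04) 0.271, with 0 members of either past the threshold over all genes or over the list alone. The cerebellum list (-0.83, adjusted p = 1.0e-06), the telencephalon list (-0.54, adjusted p = 0.00155) and the autism-associated list (-0.41, adjusted p = 0.00189) also fell, each with adjusted p = 0.271 with an estimated correlation. Cerebellum members lower over the list alone numbered 4 of 38 and included NEUROD1, a neuronal differentiation factor (-2.04, SE 0.49, adjusted p = 0.156). In the edgeR fit of only the 6 HOM and WT libraries, members past the threshold over all genes were more: 37 of 72 synapse genes were lower and 1 higher. Lower were also 15 of 39 GABAergic, 16 of 44 glutamatergic, 18 of 60 potassium and calcium channel, 5 of 18 sodium channel, 3 of 27 dopaminergic, 1 of 33 serotonergic and noradrenergic, 9 of 38 cerebellum, 3 of 23 telencephalon and 2 of 15 autism-associated genes. These falls went with the lower synapse share given above, which counts the members of the synapse list itself. They did not follow the digestive share in every library. HOM2 had a lower digestive share (0.055%) than any WT library, but its synapse share was 0.22%, against 0.459% in WT1, the lowest of WT. Without the libraries of high digestive share, which leaves HOM2 alone in HOM, the telencephalon list was at -0.33 (adjusted p = 0.153) and the autism-associated list at -0.44 (adjusted p = 0.0578). Without HOM2 these 2 lists moved further down, to -0.83 and -0.70.

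Immediate early genes, which neurons switch on within minutes of activity, held the gene that passed in this comparison. The transcription factor gene egr4 fell from 203 ± 81.3 CPM in WT to 4.72 ± 1.85 CPM in HOM (log2 change -5.43, SE 0.48, edgeR adjusted p = 0.0179), with all 3 HOM libraries below all 3 WT libraries. FOS was at 11.3 ± 8.43 CPM in HOM and 212 ± 83.1 CPM in WT (-4.23, SE 0.75, adjusted p = 0.142). BTG2, an antiproliferative early gene, was at 23.4 ± 7.22 and 139 ± 40.3 CPM (-2.56, SE 0.38, adjusted p = 0.141). JUNB (ENSDARG00000104773), an AP-1 subunit, was at 44.2 ± 7.84 and 199 ± 63.7 CPM (-2.17, SE 0.32, adjusted p = 0.141). The list fell (median -0.43, camera adjusted p = 5.1e-05), with 8 of 41 members lower when adjusted over the list alone and 1 over all genes, and adjusted p = 0.271 with an estimated correlation. In the edgeR fit of only the 6 HOM and WT libraries 8 of 41 were lower over all genes, with BTG2 at adjusted p = 0.0208 and JUNB at 0.021, and FOS had 0.0267. FOS is not among the matched members of this list. Across alternatives the adjusted p of egr4 ran from 1.7e-30 to 0.192. The call was lost without HOM1 (0.192), HOM2 (0.165) or WT1 (0.0656), with the digestive share as covariate (0.134) and without the libraries of high digestive share, with HOM2 alone in HOM (0.137), while the log2 change stayed between -5.99 and -5.21.

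**Figure D2:**
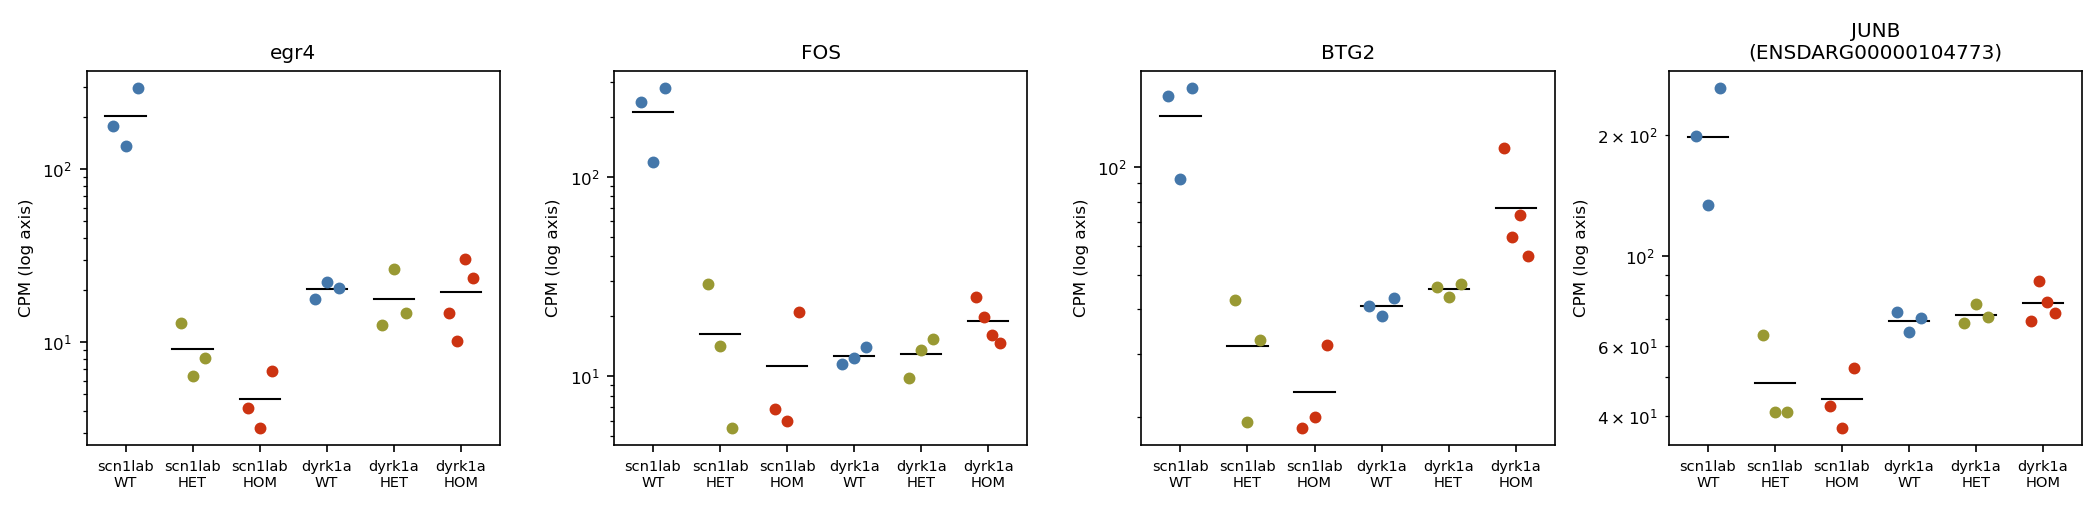
CPM of egr4, FOS, BTG2 and JUNB in each library of both lines on a log axis. The line is the group mean.

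Camera also called the hormone, peptide and glial lists lower in scn1lab HOM, none of them with an estimated correlation. The pituitary hormone list fell (median -2.14, camera adjusted p = 4.3e-04, adjusted p = 0.271 with an estimated correlation), with 3 of 11 members lower over the list alone and 0 over all genes. The somatolactin gene smtlb was at least 12.6-fold lower (0 counts in every HOM library, 2.03 ± 1.26 CPM in WT). TSHB and prl, for thyrotropin and prolactin, had log2 changes of -4.54 (SE 1.27, adjusted p = 0.162) and -2.25 (SE 0.48, adjusted p = 0.156). The neuropeptide list fell (median -1, adjusted p = 3.8e-05, adjusted p = 0.451 with an estimated correlation), with 3 of 49 lower over the list alone and 0 over all genes. Among them pmchl, a melanin-concentrating hormone gene, was at 15.3 ± 2.32 CPM in HOM and 140 ± 20.9 CPM in WT (-3.19, SE 0.77, adjusted p = 0.156). The astroglia and radial glia list fell (median -0.31, adjusted p = 0.00128, adjusted p = 0.271 with an estimated correlation; 7 of 42 lower over the list alone, 0 over all genes). GJA1, the connexin of astrocytes, was at 63.3 ± 5.62 CPM in HOM and 165 ± 67.3 CPM in WT. The oligodendrocyte and myelin list (median -0.45, adjusted p = 0.0199, adjusted p = 0.271 with an estimated correlation) went both ways, with 4 of 25 lower and 3 higher over the list alone and 0 over all genes. The myelin lipid enzyme genes UGT8 (1.45, SE 0.27, adjusted p = 0.144) and FA2H (1.5, SE 0.39, adjusted p = 0.16) were among the higher ones. In the edgeR fit of only the 6 HOM and WT libraries, 4 of 11 pituitary hormone, 12 of 48 neuropeptide, 9 of 42 astroglia and 4 of 25 oligodendrocyte genes were lower over all genes, and 1 neuropeptide and 2 oligodendrocyte genes higher. Without the libraries of high digestive share, which leaves HOM2 alone in HOM, the astroglia list was at -0.16 (adjusted p = 0.309) and the oligodendrocyte list at -0.45 (adjusted p = 0.131). The astroglia median was -0.73 without HOM2, -0.53 without WT2 and -0.48 without WT3, and the oligodendrocyte median -0.74 without HOM2, -0.75 without WT1 and -0.70 without WT2.

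Camera called skin and immune lists higher in scn1lab HOM. The skin and epithelium list rose (median 0.94, camera adjusted p = 8.1e-10, adjusted p = 0.271 with an estimated correlation), with 15 of 42 members higher and 1 lower over the list alone and 0 over all genes. An example is anxa1c, of the annexin A1 family, at 587 ± 174 CPM in HOM and 100 ± 6.77 CPM in WT (2.55, SE 0.33, adjusted p = 0.0862). The envoplakin gene evpla was also higher (1.34, SE 0.30, adjusted p = 0.156). Among pigment cell genes, pmela was at 309 ± 47.5 and 54.2 CPM (2.51, SE 0.29, adjusted p = 0.0619) and TYRP1 (ENSDARG00000056151) at 936 ± 241 and 138 ± 19.6 CPM (2.76, SE 0.48, adjusted p = 0.141). The pigment list as a whole did not pass (median 0.12, adjusted p = 0.0761), though it did without HOM2 (0.53, adjusted p = 0.00628), WT2 (adjusted p = 0.0295) or WT3 (0.21, adjusted p = 0.0155), with 6 of 23 higher and 2 lower over the list alone and 0 over all genes. The interferon and antigen presentation list (median 0.89, adjusted p = 3.8e-06) and the cytokine list (0.74, adjusted p = 2.7e-05) rose, as did the neutrophil list (1.11, adjusted p = 0.00189), each with adjusted p = 0.271 with an estimated correlation. The microglia and macrophage list rose too (0.92, adjusted p = 9.2e-04, adjusted p = 0.451 with an estimated correlation). Over the list alone 0 of 47 interferon, 1 of 55 cytokine, 1 of 18 neutrophil and 0 of 57 microglia genes passed, and 0 over all genes. The chemokine gene ccl20a.3 was at 7.42 ± 3.83 CPM in HOM and 0.792 ± 0.362 CPM in WT (3.22, SE 0.57, adjusted p = 0.142). In the edgeR fit of only the 6 HOM and WT libraries, 18 of 42 skin genes were higher and 1 lower over all genes, with anxa1c at adjusted p = 0.0188, and 7 of 22 pigment genes higher and 2 lower, with pmela at 0.0188. Higher were also 6 of 43 interferon, 5 of 54 cytokine, 1 of 16 neutrophil and 8 of 55 microglia genes. With the digestive share as covariate the microglia list was at 0.33 (adjusted p = 0.00355), the neutrophil list at 0.72 (adjusted p = 0.00541) and the cytokine list at 0.61 (adjusted p = 3.3e-05). Without the libraries of high digestive share they were at 0.20 (adjusted p = 0.231), 0.42 (adjusted p = 0.143) and 0.40 (adjusted p = 2.3e-04). That removal leaves HOM2 alone in HOM, with the spread taken from the other groups, and so does not tie these lists to the digestive share.

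Tissue, metabolic and housekeeping lists complete this comparison. The digestive organ list rose (median 4.43, adjusted p = 8.2e-05, adjusted p = 0.538 with an estimated correlation; 15 of 50 members over the list alone, 0 over all genes). It was not called without HOM3 (2.32, adjusted p = 0.0556). Its score was 6.79 ± 3.92 in HOM and 3.52 ± 1.01 in WT (exact two-sided permutation p = 0.4). The lens list rose (4.54, adjusted p = 7.9e-04), with medians of 1.52 without HOM2 and 6.91 without WT3. The lens score was 2.41 ± 2.34 in HOM and 0.61 ± 0.59 in WT (exact two-sided permutation p = 0.4). In both scores 2 HOM libraries lay above all WT libraries and 1 below all of them. The photoreceptor list fell (-3.69, and -3.65 with genes at 0 in a group at their bound, adjusted p = 3.9e-05), but was not called without the libraries of high digestive share, with HOM2 alone in HOM (adjusted p = 0.0704). Its score overlapped between the groups, with 0 HOM libraries below all WT libraries (exact two-sided permutation p = 0.4), as the share in WT1 lay within the HOM range. The cartilage and bone list fell (-0.30, adjusted p = 0.016), but not without HOM2 (-0.48, adjusted p = 0.117) or WT1 (-0.22, adjusted p = 0.266). Its median was -0.46 without WT2 and -0.66 without WT3. Each of these 3 lists had adjusted p = 0.538 with an estimated correlation. Ribosomal protein genes rose (0.59, adjusted p = 9.0e-08, adjusted p = 0.538 with an estimated correlation; 0.35 without WT3). Their unscaled share of counts overlapped between the groups (7.31 ± 1.61% in HOM, 6.51 ± 0.684% in WT). The TMM factors, which enter the log2 changes but not the shares, ran from 0.752 to 1.152 in HOM and from 1.204 to 1.35 in WT. Oxidative phosphorylation genes rose (0.37, adjusted p = 4.0e-05, adjusted p = 0.535 with an estimated correlation; 0.22 without HOM3, 0.24 without WT2, 0.13 without WT3). Stress genes rose (0.33, adjusted p = 0.015, adjusted p = 0.451 with an estimated correlation), but not without HOM3 (0.18, adjusted p = 0.156), and the median was 0.17 without WT2. Cholesterol synthesis genes rose (0.59, adjusted p = 0.0375, adjusted p = 0.54 with an estimated correlation), but not without HOM3 (adjusted p = 0.272), HET1 (0.0725) or HET2 (0.0523). The medians were 0.38 without WT2 and 0.37 without WT3. The circadian clock list fell (-0.44, adjusted p = 0.00118, -0.71 without WT1) and so did the glycolysis and hypoxia list (-0.14, adjusted p = 0.0375), each with adjusted p = 0.431 with an estimated correlation. The glycolysis list was not called without HOM2 (-0.29, adjusted p = 0.154), WT2 (-0.25, adjusted p = 0.11) or WT3 (-0.18, adjusted p = 0.0517). Its median was -0.26 without HOM3 and -0.35 without WT1. Not past the threshold were cell proliferation (0.09, adjusted p = 0.137), p53 and apoptosis (0.24, adjusted p = 0.137), complement (1.80, adjusted p = 0.694), skeletal muscle (0.15, adjusted p = 0.204), erythrocyte (0.46, adjusted p = 0.287) and endothelium (0.41, adjusted p = 0.187). Of these, complement was called lower with the digestive share as covariate (-1.77, adjusted p = 5.6e-04) and higher without HOM2 (2.23, adjusted p = 6.5e-06). Called higher without 1 library were proliferation without HOM1 (adjusted p = 0.0387) or WT1 (0.00474) and muscle without HOM1 (0.0441) or WT1 (0.033). So were erythrocyte without HOM2 (0.0478) and endothelium without HOM2 (0.0396) or WT3 (0.0385).

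In total 30 of 37 lists passed in scn1lab HOM against WT (11 higher, 19 lower), 0 with an estimated correlation and 0 by fry (smallest adjusted p = 0.0749). Of 21466 genes tested in edgeR, 1 passed (egr4, lower), while 4057 had an unadjusted p under 0.05 (2104 higher, 1953 lower) where chance alone would give 1073. DESeq2 called 1574 genes (769 higher, 805 lower), limma with quality weights 3007, edgeR on the 6 compared libraries 2077 (888 higher, 1189 lower) and the fit of all 19 libraries 1278. Most single genes whose values in the fit of 6 libraries are given above were named for their values in these same libraries. As that fit called many genes in and outside the lists, small member counts from it do not set a list apart from other genes. The edgeR count was 0 without HOM1, HOM2 or WT1, 3 without HOM3, 6 without HET3 and 171 without HET1.

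**Figure D3:**
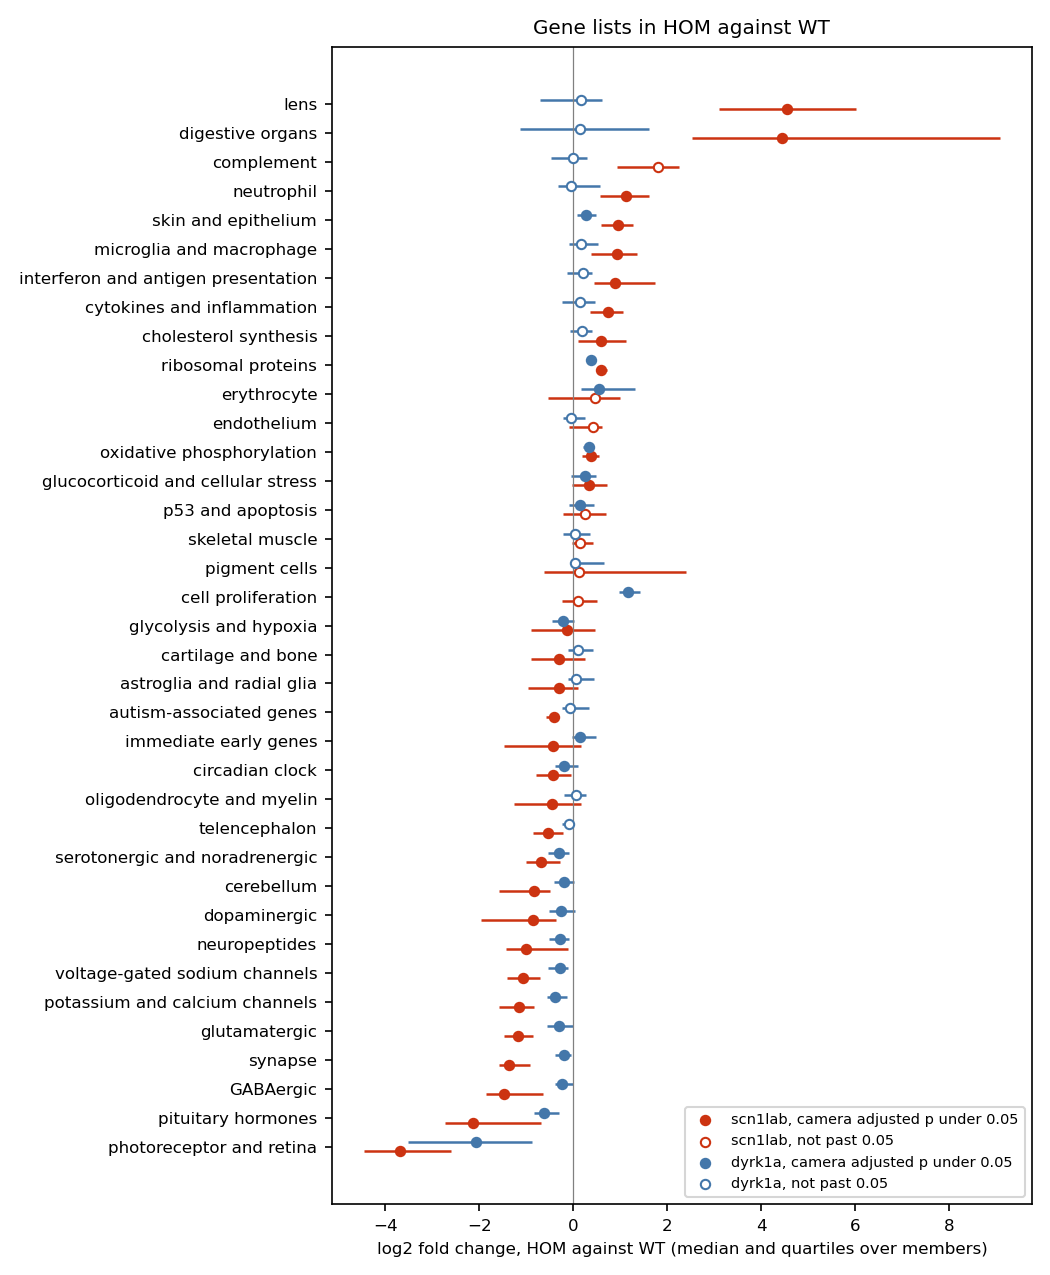
Median and quartiles of the log2 change of each gene list in HOM against WT in both lines. Filled symbols mark a camera adjusted p under 0.05.

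The comparison of scn1lab HET with WT, which uses the same WT libraries, asks whether loss of 1 copy leaves a mark. The genes with the smallest unadjusted p, none past the threshold, were pcdh2ab2, egr4 and JUNB. The protocadherin gene pcdh2ab2 had 0 counts in every HET library and 2.87 ± 0.531 CPM in WT (at least 16.8-fold lower, edgeR adjusted p = 0.341). Among early response genes egr4 was at 9.16 ± 3.4 CPM in HET and 203 ± 81.3 CPM in WT (log2 change -4.47, SE 0.46, edgeR adjusted p = 0.0653). JUNB was at 48.5 ± 13 and 199 ± 63.7 CPM (-2.03, SE 0.32, adjusted p = 0.341), and egr1 at 26.6 ± 6.79 and 80.8 ± 18.7 CPM (-1.60, SE 0.28, adjusted p = 0.341), with every HET library below every WT library. The immediate early list fell (median -0.58, camera adjusted p = 4.2e-06, adjusted p = 0.351 with an estimated correlation), with 6 of 41 members lower over the list alone and 0 over all genes. Neuronal lists fell as well: synapse (-0.78, adjusted p = 7.5e-13), GABAergic (-1.02, adjusted p = 1.0e-09), glutamatergic (-0.74, adjusted p = 9.8e-09) and potassium and calcium channels (-0.95, adjusted p = 2.2e-13), each with adjusted p = 0.351 with an estimated correlation and 0 members past the threshold over all genes. Over the list alone 3 of 45 glutamatergic genes were lower, among them SLC17A8 (0.232 ± 0.238 CPM in HET, 4.80 ± 0.867 CPM in WT) and SLC17A6 (ENSDARG00000041150, 51.5 ± 22.4 and 136 ± 19.4 CPM), which load glutamate into vesicles. Without HET1 the synapse and glutamatergic medians were -0.43 each. Without the libraries of high digestive share, which leaves HET3 alone in HET, the synapse list was at -0.52 (adjusted p = 0.148). The telencephalon list fell (-0.68, adjusted p = 1.7e-06, adjusted p = 0.351 with an estimated correlation), with 2 of 23 members lower over the list alone and 0 over all genes. They were TBR1, a transcription factor of pallial neurons (-1.36, SE 0.34, adjusted p = 0.341), and EOMES (ENSDARG00000006640; -1.70, SE 0.44, adjusted p = 0.341). The dopaminergic list fell (-0.50, adjusted p = 0.0249, adjusted p = 0.507 with an estimated correlation), but not without HET1 (-0.49, adjusted p = 0.563) or WT3 (-0.03, adjusted p = 0.317). Its median was -0.87 without WT1 and -0.86 without WT2.

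Camera called skin, ribosomal and immune lists higher in scn1lab HET, none of them with an estimated correlation. The list scores of skin, microglia and interferon lay above all WT libraries in 2 of 3 HET libraries each (exact two-sided permutation p = 0.3, 0.2 and 0.2), and the ribosomal score in 3 (p = 0.1, the smallest possible). Keratin gene krt17 was at 1460 ± 470 CPM in HET and 476 ± 208 CPM in WT (1.61, SE 0.39, adjusted p = 0.341). The skin list rose (median 0.66, adjusted p = 1.1e-08, adjusted p = 0.351 with an estimated correlation; 10 of 42 over the list alone, 0 over all genes). Ribosomal protein genes rose (1.42, adjusted p = 1.9e-28, adjusted p = 0.351 with an estimated correlation), with 76 of 80 higher over the list alone and 0 over all genes. The median was 0.57 without HET3, the library with a ribosomal share of 20%. Oxidative phosphorylation genes rose (0.65, adjusted p = 9.3e-14, adjusted p = 0.352 with an estimated correlation; 0.37 without HET3). The microglia list rose (0.66, adjusted p = 4.0e-04, adjusted p = 0.466 with an estimated correlation), but not without HET1 (0.35, adjusted p = 0.0541), and its median was 0.38 without WT3. The interferon list rose (0.79, adjusted p = 6.4e-04, adjusted p = 0.352 with an estimated correlation), but not without HET1 (0.47, adjusted p = 0.0608), and its median was 0.48 without WT3. Complement genes rose (2.79, adjusted p = 2.9e-06, adjusted p = 0.352 with an estimated correlation; 4.59 without WT2) together with digestive organ genes (3.60, adjusted p = 1.1e-08, adjusted p = 0.457 with an estimated correlation; 2.35 without HET2). With the digestive share as covariate the complement list was at -0.38 (adjusted p = 0.927). For the neuropeptide list, which camera called lower (adjusted p = 0.0215, adjusted p = 0.643 with an estimated correlation), the median was -0.04 but the mean 0.06. The call was lost without HET1 (0.23, adjusted p = 0.184), WT2 (-0.16, adjusted p = 0.113) or WT3 (-0.03, adjusted p = 0.104). Leaving out other libraries moved this median to between -0.53 (without HET3) and -0.09 (without HOM1), with -0.29 without WT1, -0.13 without HOM2 and -0.10 without HET2.

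Altogether 27 of 37 lists passed in scn1lab HET against WT (12 higher, 15 lower), 0 with an estimated correlation and 0 by fry. Of single genes edgeR called 0 (smallest adjusted p = 0.0653), with 2833 at an unadjusted p under 0.05 where chance would give 1073. DESeq2 called 338 (180 higher, 158 lower), limma with quality weights 0, and edgeR without the libraries of high digestive share, with HET3 alone in HET, 3564.

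The comparison of scn1lab HOM with HET asks what the loss of the remaining copy adds. The gene si:dkey-73p2.2, singled out after its value was seen, fell from a mean of 71 CPM in HET to 1.79 ± 0.569 CPM in HOM (log2 change -5.30, SE 0.45, edgeR adjusted p = 0.012). All 3 WT libraries lay between the HOM and HET libraries. Its adjusted p ran from 3.5e-29 to 0.23 across alternatives. The call was lost without HOM1 (0.23), HOM2 (0.12), HOM3 (0.0551), WT1 (0.0508) or WT2 (0.0507), in the fits of 6 (0.212) and 19 (0.213) libraries and with quality weights (0.0616). In these settings the log2 change stayed between -5.54 and -5.02. The pigment cell gene pmela, which did not pass, was at 309 ± 47.5 CPM in HOM and 51.5 ± 10.8 CPM in HET (2.59, SE 0.29, adjusted p = 0.0742). The pigment cell list rose (median 0.44, camera adjusted p = 0.0142, adjusted p = 0.96 with an estimated correlation), with 8 of 23 members higher and 3 lower over the list alone and 0 over all genes. The pigment median was 0.23 without HOM1, 0.72 without HOM2, 0.74 without HET1 and 0.08 without HET3. The hormone gene pmchl was at 15.3 ± 2.32 CPM in HOM and 422 ± 502 CPM in HET (-4.78, SE 0.83, adjusted p = 0.919). The gene pcdh2ab2, a protocadherin gene with 0 counts in every HET library, was at least 6.83-fold higher in HOM (adjusted p = 0.919). The annexin gene anxa1b was at 43.9 ± 6.88 CPM in HOM and a mean of 209 CPM in HET (-2.25, SE 0.36, adjusted p = 0.855).

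Among groups, cell proliferation genes rose in scn1lab HOM against HET (median 0.44, camera adjusted p = 3.2e-07), but not without HET1 (0.29, adjusted p = 0.288), and the median was 0.85 without HET2. Ribosomal protein genes fell (-0.87, adjusted p = 3.4e-18) and oxidative phosphorylation genes fell (-0.24, adjusted p = 3.9e-06). Without HET3 their medians were 0.01 (adjusted p = 0.864) and -0.02 (adjusted p = 0.877), and the latter was -0.40 without HOM3 and -0.43 without HET1. The synapse list fell (-0.54, adjusted p = 0.0167), but not without HOM3 (-0.46, adjusted p = 0.276), HET2 (-0.36, adjusted p = 0.795) or HET3 (-0.27, adjusted p = 0.999). Its median was -0.88 without HET1. Each of these lists had adjusted p = 0.96 with an estimated correlation and 0 members past the threshold over all genes or over the list alone. Of 37 lists 14 passed (5 higher, 9 lower; 8 without HET3), 0 with an estimated correlation and 0 by fry. Of genes edgeR called 1 and had 915 at an unadjusted p under 0.05 where chance would give 1073. DESeq2 called 58 (32 higher, 26 lower) and limma with quality weights 0. The edgeR count was 0 without HOM1, HOM2, HOM3, WT1 or WT2, 2 without HET1 and 3 without HET3. The fit without the libraries of high digestive share sets HOM2 alone against HET3 alone. Its count therefore cannot part genotype from library.

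The comparison of dyrk1a HOM with WT asks what loss of this kinase does. The score of the cell proliferation list was higher in all 4 HOM libraries than in the 3 WT libraries, though none of its members passed over all genes. RRM1 and TK1, which supply nucleotides for DNA synthesis, were at 44.7 ± 3.81 CPM in HOM (n = 4) and 19.6 ± 4.35 CPM in WT (n = 3; log2 change 1.19, SE 0.19) and at 15.9 ± 2.58 and 5.67 ± 1.46 CPM (1.48, SE 0.25). The chromatin assembly gene chaf1a was at 47.2 ± 13 and 17.6 ± 6.31 CPM (1.43, SE 0.29), and each of the 3 had edgeR adjusted p = 0.449. DCTPP1, a nucleotide pyrophosphatase gene, had a log2 change of 1.46 (SE 0.25, adjusted p = 0.449). The proliferation list rose (median 1.17, camera adjusted p = 4.1e-46), with 48 of 63 members higher when adjusted over the list alone and 0 over all genes. It had adjusted p = 0.164 with an estimated correlation and 0.0688 by fry. Its list score was 4.64 ± 0.3 in HOM and 3.58 ± 0.49 in WT (exact two-sided permutation p = 0.0571, the smallest possible for 4 against 3). Against the 6 HET and WT libraries together, a comparison added for this list alone after the rise was seen, the score was 3.55 ± 0.32 and the exact two-sided permutation p, unadjusted, was 0.00952. No marker list of skin, muscle or cartilage moved as far: their medians were 0.27, 0.04 and 0.11. The muscle and cartilage lists were called higher without HOM3 (0.36, adjusted p = 2.3e-04, and 0.29, adjusted p = 0.038) and with a replicate block (0.36, adjusted p = 0.0132, and 0.18, adjusted p = 0.0492). The muscle list was called lower without HOM1 (-0.21, adjusted p = 8.2e-04), HOM2 (-0.14, adjusted p = 0.00562) or WT1 (-0.12, adjusted p = 0.0312).

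**Figure D4:**
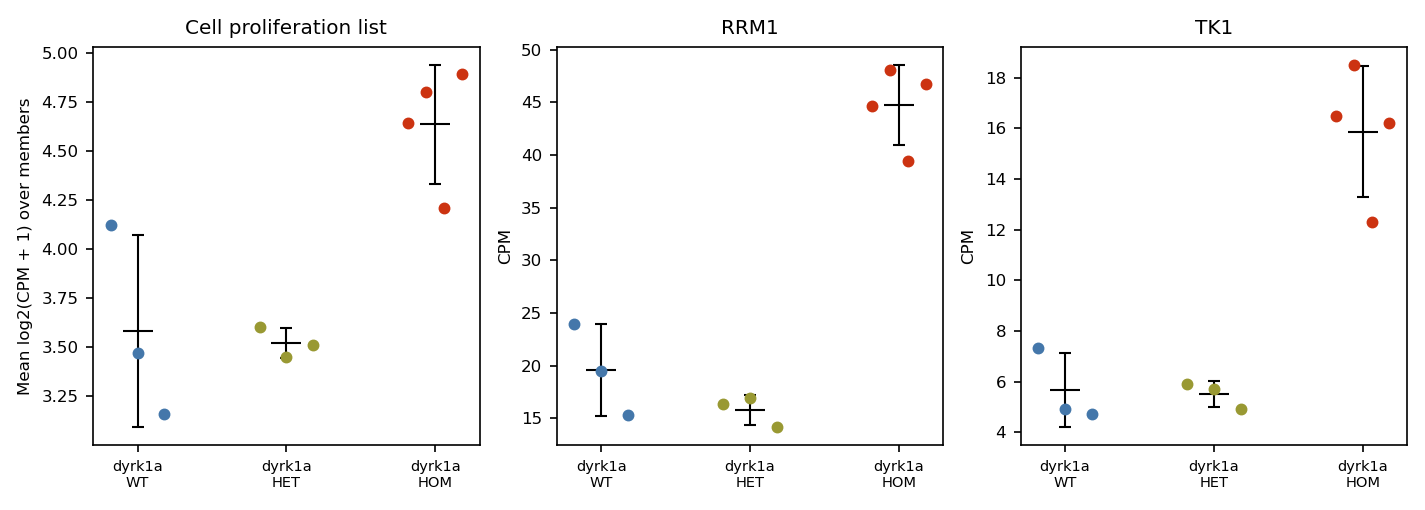
Score of the cell proliferation list and CPM of RRM1 and TK1 in each dyrk1a library. Bars are mean ± SD.

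Stress genes rose in dyrk1a HOM and glycolysis genes fell. The glucocorticoid and cellular stress list (median 0.24, camera adjusted p = 9.4e-05, adjusted p = 0.164 with an estimated correlation) had 4 of 60 members higher over the list alone and 0 over all genes. FKBP5, which glucocorticoids induce, was at 59.9 ± 24.1 CPM in HOM and 15.4 ± 5.26 CPM in WT (1.96, SE 0.42). DDIT3 was at 480 ± 74.3 and 267 ± 43.7 CPM (0.84, SE 0.17) and atf4a at 106 ± 30.3 and 53.2 ± 6.85 CPM (0.99, SE 0.24), the latter a pair of factors of the integrated stress response, all with edgeR adjusted p = 0.449. The glycolysis and hypoxia list fell (-0.22, adjusted p = 3.2e-05, adjusted p = 0.0982 with an estimated correlation, 0.0311 by fry), with 0 of 56 members past the threshold over all genes or over the list alone. Its score was lower in all 4 HOM libraries than in the WT libraries (5.08 ± 0.04 and 5.30 ± 0.06, exact two-sided permutation p = 0.0571). The p53 and apoptosis list rose (0.14, adjusted p = 0.00905, adjusted p = 0.345 with an estimated correlation). So did ribosomal protein (0.37, adjusted p = 2.0e-17; 0.23 without HOM5) and oxidative phosphorylation genes (0.34, adjusted p = 2.9e-11; 0.18 without HOM5), each with adjusted p = 0.544 with an estimated correlation.

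Camera called lists of neurons and their signals lower in dyrk1a HOM, none of them with an estimated correlation. Of single genes, none of which passed, SCN3B, a sodium channel beta subunit gene, was at 1.96 ± 1.02 CPM in HOM and 15.9 ± 7.1 CPM in WT (-3.02, SE 0.51, adjusted p = 0.449). The hypothalamic peptide gene npvf was at 7.42 ± 3.15 and 21.3 ± 6.06 CPM (-1.53, SE 0.32, adjusted p = 0.449). The sodium channel list fell (-0.28, adjusted p = 3.4e-05, adjusted p = 0.211 with an estimated correlation; 1 of 17 over the list alone, 0 over all genes). The neuropeptide list fell (-0.29, adjusted p = 1.7e-07, adjusted p = 0.345 with an estimated correlation; 1 of 50 and 0). The synapse list fell (-0.20, adjusted p = 1.7e-05, adjusted p = 0.544 with an estimated correlation; 0 of 71 and 0). Its median was -0.11 without HOM1, -0.08 without HOM2, -0.34 without HOM3 and -0.35 without HOM5. The scores of the synapse (4.44 ± 0.38 in HOM, 4.69 ± 0.09 in WT), GABAergic (3.95 ± 0.39, 4.21 ± 0.05) and glutamatergic lists (3.48 ± 0.47, 3.82 ± 0.08) overlapped, with 1 HOM library above all WT libraries in each (exact two-sided permutation p = 0.514, 0.514 and 0.4). All 4 HOM libraries scored below all WT libraries for sodium channels (3.88 ± 0.21 in HOM, 4.37 ± 0.09 in WT). The same held for the serotonergic and noradrenergic (2.7 ± 0.1, 2.92 ± 0.12) and pituitary hormone lists (2.69 ± 0.08, 3.09 ± 0.16). Each of these had exact two-sided permutation p = 0.0571. The dopaminergic list fell (-0.27, adjusted p = 0.0102, adjusted p = 0.54 with an estimated correlation; 0 of 28 and 0), but not without HOM2 (-0.18, adjusted p = 0.191) or WT4 (-0.15, adjusted p = 0.075). Its median was -0.46 without HOM3. Its score was 2.68 ± 0.2 in HOM and 2.92 ± 0.16 in WT (exact two-sided permutation p = 0.171). Immune lists did not pass: microglia (0.16, adjusted p = 0.156), neutrophil (-0.05, adjusted p = 0.915), complement (0.00, adjusted p = 0.915), interferon (0.20, adjusted p = 0.182) and cytokines (0.15, adjusted p = 0.466). With 1 surrogate variable the complement list was called lower (-0.14, adjusted p = 3.5e-04) and the microglia list higher (0.18, adjusted p = 0.0227), the latter also without HOM3 (0.22, adjusted p = 0.0225). With a replicate block complement (1.29, adjusted p = 2.8e-04) and cytokines (0.13, adjusted p = 0.0494) were called higher, and with no filter interferon (0.24, adjusted p = 0.0482). Photoreceptor genes fell (-2.06, adjusted p = 2.2e-05, adjusted p = 0.544 with an estimated correlation), with a median of -1 without WT1. Their share was 0.142 ± 0.011% in HOM and 0.334 ± 0.228% in WT, and WT2 (0.132%) lay within the HOM range. The score overlapped too, with 0 HOM libraries below all WT libraries (exact two-sided permutation p = 0.286).

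Altogether 21 of 37 lists passed in dyrk1a HOM against WT (8 higher, 13 lower), 0 with an estimated correlation and 1, glycolysis and hypoxia, by fry. Of 21025 genes edgeR called 0 (smallest adjusted p = 0.449; 3 without WT2), with 1640 at an unadjusted p under 0.05 (954 higher, 686 lower) where chance would give 1051. DESeq2 called 162 (125 higher, 37 lower) and limma with quality weights 0.

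The comparison of dyrk1a HET with WT, which shares the WT libraries, asks about a partial loss. PTCD1, a mitochondrial RNA-binding protein gene, was at 14.3 ± 3.64 CPM in HET and 37.7 ± 1.33 CPM in WT (log2 change -1.40, SE 0.24). GPR158 (ENSDARG00000079665), an orphan receptor gene, was at 27.1 ± 12.2 and 4.59 ± 0.647 CPM (2.56, SE 0.46), and scarb2a, a lysosomal membrane protein gene, at 39.9 ± 6.12 and 20.1 ± 1.84 CPM (0.99, SE 0.20), each of the 3 with edgeR adjusted p = 1. The proliferation list did not pass (median -0.14, camera adjusted p = 0.51), but was called higher without WT1 (0.28, adjusted p = 0.00291) and lower without WT4 (-0.37, adjusted p = 2.4e-05). The skin list rose (0.34, adjusted p = 8.6e-07; 0.21 without HET2), and so did ribosomal protein genes (0.24, adjusted p = 9.9e-12), each with adjusted p = 0.598 with an estimated correlation. Digestive organ genes (4.88, adjusted p = 8.6e-07) and complement genes (4.13, adjusted p = 0.0117) rose together, each with adjusted p = 0.598 with an estimated correlation. Without HET4, the library with a digestive share of 6.26%, their medians were -0.43 (adjusted p = 0.019) and 0.22 (adjusted p = 0.116). Skeletal muscle genes rose (0.54, adjusted p = 9.7e-05, adjusted p = 0.629 with an estimated correlation), but not without HET2 (0.21, adjusted p = 0.277), and the median was 0.34 without WT1 and 0.90 without WT4. The dopaminergic list did not pass (0.06, adjusted p = 0.648). Of 37 lists 21 passed (11 higher, 10 lower; 11 without HET2), 0 with an estimated correlation and 0 by fry. Of genes edgeR called 0 (smallest adjusted p = 1; 1 without HOM2 or HET3, 3 without WT2), with 700 at an unadjusted p under 0.05 where chance would give 1051. DESeq2 called 28 (16 higher, 12 lower) and limma with quality weights 0.

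The comparison of dyrk1a HOM with HET asks what the loss of the remaining copies adds. Cell proliferation genes were again higher as a list, though no gene passed. RRM1 was at 44.7 ± 3.81 CPM in HOM (n = 4) and 15.9 ± 1.46 CPM in HET (n = 3; log2 change 1.49, SE 0.19, edgeR adjusted p = 0.16). TPX2, a spindle assembly factor, was at 26.9 ± 6.97 and 7.41 ± 0.69 CPM (1.86, SE 0.32, adjusted p = 0.408). Also higher were her15.2, of a family of Notch target genes, at 22.8 ± 7.17 and 6.68 ± 1.06 CPM (1.77, SE 0.27, adjusted p = 0.408), and lgals3bp.1 at 26.1 ± 7.75 and 8.38 ± 2.26 CPM (1.64, SE 0.27, adjusted p = 0.408). The pigment gene SLC24A5, with 0 counts in every HET library, was at least 6.11-fold higher in HOM. The proliferation list rose (median 1.31, camera adjusted p = 1.4e-53, adjusted p = 0.307 with an estimated correlation, 0.0912 by fry), with 51 of 63 members higher over the list alone and 0 over all genes. Its score was 4.64 ± 0.3 in HOM and 3.52 ± 0.08 in HET (exact two-sided permutation p = 0.0571). The glycolysis list fell (-0.10, adjusted p = 0.0105, adjusted p = 0.307 with an estimated correlation), but not without HOM2 (-0.12, adjusted p = 0.0535) or HET4 (-0.09, adjusted p = 0.0743). Its median was -0.21 without HOM3 and -0.17 without HET2. The dopaminergic list fell (-0.21, adjusted p = 0.00736, adjusted p = 0.715 with an estimated correlation), but not without HOM2 (-0.11, adjusted p = 0.136), and its median was -0.43 without HOM1 and -0.35 without HOM5. Skeletal muscle genes fell (-0.49, adjusted p = 3.0e-07, adjusted p = 0.881 with an estimated correlation), but not without HOM3 (-0.18, adjusted p = 0.483), the library with a muscle share of 0.667%, and the median was -0.80 without HOM1 and -0.18 without HET2. Of 37 lists 17 passed (4 higher, 13 lower), 0 with an estimated correlation and 0 by fry. The count was 8, 7 and 8 without HOM1, HOM2 and HET4. Of genes edgeR called 0 (smallest adjusted p = 0.16; 1 without HOM2 or HET3), with 1389 at an unadjusted p under 0.05 where chance would give 1051. DESeq2 called 157 (129 higher, 28 lower) and limma with quality weights 0.

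The lines were then compared with each other, the question of shared pathways that the series poses. The HOM effect on early response genes differed between the lines: the difference in log2 change (dyrk1a minus scn1lab) was 5.38 for egr4 (SE 0.62, edgeR adjusted p = 0.00241), 4.81 for FOS (SE 0.74, adjusted p = 0.0278), 3.47 for BTG2 (SE 0.44, adjusted p = 0.00451) and 2.30 for JUNB (SE 0.32, adjusted p = 0.00894). In dyrk1a, egr4 was at 19.6 ± 8.96 CPM in HOM and 20.2 ± 2.27 CPM in WT. The skin gene anxa1c differed the other way (-2.42, SE 0.38, adjusted p = 0.0286) and zgc:122979 by 4.1 (SE 0.57, adjusted p = 0.00894). In all 6 genes passed (5 higher, 1 lower) and 2428 had an unadjusted p under 0.05 where chance would give 1124. The immediate early list differed with a median of 0.82 (camera adjusted p = 1.2e-08) and was the only list call of all comparisons that held with an estimated correlation (adjusted p = 0.0185), and fry gave adjusted p = 7.4e-04. Of its 41 members 9 were higher over the list alone and 3 over all genes. Its score in scn1lab was 3.84 ± 0.03 in HOM and 4.51 ± 0.18 in WT (exact two-sided permutation p = 0.1). In dyrk1a it was 4.27 ± 0.11 in HOM and 4.08 ± 0.06 in WT (exact two-sided permutation p = 0.0571), with all 4 HOM libraries above all WT libraries. The list difference thus joins a fall in scn1lab with a smaller rise in dyrk1a. Of 37 lists 25 differed (17 higher, 8 lower). DESeq2 called 260 genes and limma with quality weights 64. The edgeR count was 3 without dyrk1a WT1 or WT4, 10 without scn1lab HET2, 13 without HET3 and 67 without HET1.

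Over all genes the HOM effects of the lines were weakly correlated. Across 20310 genes the Pearson correlation of the log2 changes was 0.35 and 61.6% of the genes had the same sign. For differences of group means it was 0.33, and 9 of 700 relabellings of the libraries gave a value as large (exact one-sided permutation p = 0.013, highest other 0.38). The value moved to 0.22 without scn1lab HOM3, 0.23 without dyrk1a HOM1 and 0.10 without the libraries of high digestive share. In edgeR 0 genes passed in HOM of both lines, and 422 had an unadjusted p under 0.05 in both, against 310 for independent lists, 389 of them in the same direction. In DESeq2 17 genes passed in both, 3 of them in opposite directions. Higher in both were 10 where 4.44 were expected (Fisher exact one-sided p = 0.0138). Lower in both were 4 where 1.44 were expected (Fisher exact one-sided p = 0.0548). The Fisher test treats genes as independent, and no relabelling of the libraries was run for this overlap. DESeq2 also called 59 and 60 unchanged genes in the simulated scn1lab and dyrk1a HOM against WT comparisons. The Fisher p-values therefore do not decide whether the lines share changed genes. Among those higher in both, picked after their values were seen, were GINS2, a replication factor gene (1.58 in scn1lab and 1.51 in dyrk1a), REL, an NF-kappaB subunit gene (1.75 and 1.38), and irg1l (3.46 and 3.58). By edgeR tmem176l.4 was at 519 ± 132 CPM in scn1lab HOM and 135 ± 47.2 CPM in WT (1.94, SE 0.40, adjusted p = 0.149) and at 343 ± 29.3 and 189 ± 17.1 CPM in dyrk1a (0.86, SE 0.21, adjusted p = 0.449). The gene plekhs1.3 had log2 changes of 2.32 (SE 0.48, adjusted p = 0.149) in scn1lab and 0.66 (SE 0.15, adjusted p = 0.449) in dyrk1a. BTG2 was among the genes with opposite directions (-2.61 and 0.91). For the dopaminergic list, which camera called lower in HOM of both lines, the difference between the lines was 0.60 (adjusted p = 0.00937, adjusted p = 0.437 with an estimated correlation), but it was not called without scn1lab WT3 (0.44, adjusted p = 0.154), and it was 1.15 without scn1lab HOM2 and 0.94 without scn1lab WT1.

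Over the 259 pairs of a list and a comparison, the sign of the median, the mean or the camera direction differed in 26, of which 1 passed the camera threshold: the neuropeptide list in scn1lab HET against WT.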

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

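The tests of a smaller brain share, of handling and of other tissues in dyrk1a HOM, digestive organs among them, were chosen after their results were seen. Those of digestive carry-over in scn1lab HOM, of 1 library alone and of other splits were written down before their own results, but the digestive covariate was added after seeing the data.

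Lower neuronal lists in scn1lab HOM. The synapse list (median -1.37) fell while the digestive share rose, so carry-over of digestive tissue could dilute brain RNA. With the log2 digestive share as covariate the median was -1.24 (quartiles -1.55 and -0.76), which argues against carry-over as the whole cause. It does not exclude it. The share was higher in HOM1 and HOM3 than in any WT library, so the fit cannot fully part it from genotype. A smaller brain share in the head might lower neuronal and raise skin genes. With the other tissues in unchanged proportion it would raise cartilage genes alongside skin genes. The lower quartile of the skin list lay 0.35 above the upper quartile of the cartilage list, whose fall depended on single libraries. That argues only against a smaller brain share with the other tissues in unchanged proportion. A smaller brain share with the other tissues in changed proportion cannot be judged by this test and stays open. Lower expression per cell, delayed maturation of neurons and a change in skin itself also stay open and untested.

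Lower early response genes in scn1lab HOM. The 8 of 41 members picked because they were lower over the list alone had a median of -2.25, and with the digestive share as covariate -2.13, which argues against carry-over as the whole cause for these 8 (the whole list had -0.43 and -0.56). Handling could have raised early genes in the scn1lab WT larvae: over the same 8 the scn1lab WT libraries lay 2.44 above the dyrk1a WT libraries, and the HET and HOM libraries differed by 0.13 and -0.23. Picking these 8 favours a high scn1lab WT, and the columns of the 9 scn1lab libraries alone carry a tag that reads as a date, so a batch may also part the lines and this decides nothing. Over all 41 members the WT libraries differed by a median of 0.7 (quartiles 0.23 and 1.81). Handling or a batch that reached all scn1lab larvae alike would not part HOM from WT within the line, while handling of the WT larvae alone and genotype cannot be told apart, as the labels used here record no handling.

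Higher proliferation genes in dyrk1a HOM. A single library might carry the rise, but the lowest median with 1 library left out was 0.95. More skin, muscle or cartilage could raise these genes, but the highest upper quartile of these 3 lists was 0.49 and the lower quartile of the proliferation list 0.98. More digestive tissue would raise the digestive score, which was 2.2 in HOM and 2.26 in WT, and with the digestive share as covariate the proliferation median was 1.2. A single library is thus excluded as the whole cause. The values argue against more skin, muscle, cartilage or digestive tissue as the whole cause, as far as their marker lists show it. They do not exclude it, because these tests were chosen after their results were seen. Growth of such tissue without a rise of its markers is not covered. Other tissues (upper quartile 1.31 for erythrocyte), more dividing cells and delayed development stay open.

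The splits of the libraries into groups of the same sizes show whether chance can be excluded. The numbers of splits below include the real grouping. For genes, scn1lab HOM against WT called 1 and the highest other split 0, HET against WT 0 and 0, and HOM against HET 1 and 0. For dyrk1a HET against WT it was 0 and 3. The splits in these designs, 10 each, are too few for a share under 0.05. For dyrk1a HOM against WT the real count was 0 and the highest other split called 120, and for HOM against HET it was 0 and 3. Every split reaches a count of 0, so the splits decide nothing where the real count is 0. For the difference between the lines 6 were called, 12 of 100 splits reached that count and the highest other split called 302. Chance is thus not excluded for the count of 6. A split calling 120 or 302 genes points to a structure of the samples, whose source was not tested. For lists the real count and the highest other split were 30 and 32, 27 and 26, and 14 and 31 in scn1lab and 21 and 16 in dyrk1a HET against WT, designs whose splits are too few as above. They were 21 and 24 in dyrk1a HOM against WT (5 of 35 splits reached the real count), 17 and 22 in HOM against HET (12 of 35) and 25 and 32 between the lines (24 of 100), so chance is not excluded for these list counts.

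The dyrk1a HOM group is the only group of 4 libraries, so only it was tested for a value standing apart: 7 of its 76 sets of values held one, where chance picks out about 1 in 20. The ratios were 0.917 for the lens share, 0.887 for the erythrocyte score, 0.843 for the lens score, 0.833 for the oligodendrocyte score, 0.859 for SCN3B, 0.841 for lgals3bp.1 and 0.882 for npvf.

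The HOM effect differed between the lines (dyrk1a minus scn1lab) for zgc:122979 (4.1), BTG2 (3.47), FOS (4.81), egr4 (5.38), anxa1c (-2.42) and JUNB (2.30). Neuronal lists that differed by camera were dopaminergic (0.60), serotonergic and noradrenergic (0.42), GABAergic (1.09), glutamatergic (0.76), sodium channels (0.59), potassium and calcium channels (0.82), immediate early genes (0.82), synapse (1.12), neuropeptides (0.52), autism-associated genes (0.55), telencephalon (0.48) and cerebellum (0.62). Others were pituitary hormones (1.35), oligodendrocyte and myelin (0.65), astroglia (0.50), cell proliferation (1.09), microglia (-0.76), neutrophil (-1.07), interferon (-0.77), cytokines (-0.62), ribosomal proteins (-0.23), photoreceptor (1.33), lens (-4.95), skin (-0.69) and digestive organs (-2.52). Of these lists only the immediate early genes held with an estimated correlation (adjusted p = 0.0185).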

How the results depend on the processing

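The covariate, the removal of libraries with a high digestive share, quality weights and fry were chosen after seeing the data. Removing those libraries leaves 1 HOM and 1 HET library in scn1lab. The correlation over called genes alone was not run, as too few were called. The cause of any reversed or moved value below was not tested.

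Genes changed in scn1lab HOM against WT (1) numbered 4 with no filter, 1574 in DESeq2, 2077 with only the groups compared, 1278 with all 19 libraries, 3007 with quality weights, and 0 with the digestive covariate or without libraries of high digestive share. In HET against WT (0) they numbered 1 with upper quartile factors or no filter, 338 in DESeq2, 52 with all 19 libraries and 3564 without libraries of high digestive share. In HOM against HET (1) they numbered 58 in DESeq2, 733 without libraries of high digestive share, and 0 with quality weights or only the groups compared. In dyrk1a DESeq2 called 162, 28 and 157 in HOM against WT, HET against WT and HOM against HET. Genes that differed between the lines (6) numbered 260 in DESeq2, 21 with 1 surrogate variable, 64 with quality weights and 16 without libraries of high digestive share. The correlation between the lines (0.35) was 0.23 with no filter, 0.29 with 1 surrogate variable, 0.28 with the digestive covariate, 0.3 with quality weights and 0.1 without libraries of high digestive share. DESeq2 called 17 genes in HOM of both lines.

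With 1 library left out, gene counts ran from 0 to 171, 0 to 0 and 0 to 3 in scn1lab HOM against WT, HET against WT and HOM against HET, from 0 to 3, 0 to 3 and 0 to 1 in dyrk1a, and from 3 to 67 between the lines. The correlation ran from 0.22 to 0.41. List counts ran from 27 to 32, 18 to 30 and 8 to 18 in scn1lab, 15 to 22, 11 to 23 and 7 to 17 in dyrk1a, and 19 to 28 between the lines.

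With an estimated correlation 0 lists passed in each comparison and 1 between the lines, and by fry 0, but 1 in dyrk1a HOM against WT and 1 between the lines. In scn1lab HOM against WT 19 lists passed without libraries of high digestive share. In dyrk1a HOM against HET 11 passed with 1 surrogate variable, 11 with the digestive covariate and 8 without libraries of high digestive share.

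Camera's direction turned for the following list medians. With the digestive covariate complement was at -1.77 in scn1lab HOM against WT and digestive organs at 0.05 in dyrk1a HOM against WT. With 1 surrogate variable complement was at -0.14 and digestive organs at -0.04 in the latter. Without libraries of high digestive share cholesterol was at 0.11 and digestive organs at -2.38 in scn1lab HOM against WT, neuropeptides at 0.57 and endothelium at -0.43 in HET against WT, microglia at -0.57 in HOM against HET, and complement at 5.58, oxidative phosphorylation at 0.21 and digestive organs at 5.07 between the lines. All of these passed in the turned direction, except cholesterol and digestive organs in scn1lab HOM against WT, endothelium, and digestive organs between the lines.

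The replicate numbers did not clearly pair the samples, though pairing is not excluded. Libraries of the same number in scn1lab correlated from -0.42 to 0.14 (3 of 9 pairs above 0.1), and in dyrk1a from -0.21 to 0.32 (3 of 6). The closest match had the same number for 2 of 9 scn1lab libraries and 3 of 9 dyrk1a libraries. With a replicate block 2 genes were called in scn1lab HOM against WT and the correlation between the lines was 0.41. Muscle (0.36) and cartilage (0.18) in dyrk1a HOM against WT and oxidative phosphorylation (-0.08) and ribosomal proteins (-0.17) in HOM against HET turned direction, and all but oxidative phosphorylation passed in it.

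Where leaving out 1 library turned a list's direction, the medians over all such fits ran as follows. In scn1lab HET against WT they ran from -0.53 to 0.23 for neuropeptides and -0.62 to -0.1 for proliferation. In scn1lab HOM against HET they ran from -0.88 to -0.27 for synapse, -0.92 to 0 for neuropeptides, -1.18 to 0.01 for ribosomal proteins, 1.61 to 5.03 for lens, -0.53 to 0.17 for muscle and -0.63 to 1.89 for digestive organs. In dyrk1a HOM against WT they ran from -0.21 to 0.42 for muscle and -0.12 to 0.29 for cartilage. In dyrk1a HET against WT they ran from -0.37 to 0.28 for proliferation, -2.25 to 0.08 for photoreceptor and 0.32 to 3.75 for lens. In dyrk1a HOM against HET they ran from -0.4 to -0.11 for pituitary hormones, -0.01 to 0.28 for ribosomal proteins, -1.9 to 0.06 for photoreceptor, -4.93 to -0.61 for lens and -0.26 to 0.09 for skin. Past the threshold in the turned direction were digestive organs in scn1lab HOM against HET (1.41 without HOM2), muscle (0.36) and cartilage (0.29) without HOM3 in dyrk1a HOM against WT, proliferation without WT1 in dyrk1a HET against WT (0.28), and pituitary hormones without HET2 in dyrk1a HOM against HET (-0.4).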
